A study of Zea mays with 6 samples.

How the data were processed

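Messenger RNA of maize leaves was profiled by RNA sequencing on an Illumina NovaSeq in 6 libraries, 3 of the wild type (WT) and 3 of the edf1-D mutant, both in the inbred line W22. Per the labels' protocols, plants stood in the field and leaves were taken 25 days after germination, total RNA was isolated with a phenol-based reagent, and libraries were made with a TruSeq RNA kit. Whether that kit marked the strand is not given in the sources used here, so reads of a gene and of an antisense partner may not have been told apart. The labels do not say whether the replicates of a genotype came from separate plants or from pools. The p-values of the comparisons between genotypes therefore measure the spread between these libraries, which may be partly technical. Those of the permutation and Fisher's exact tests take genes as units and do not measure this spread.

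The deposited values are 1 number per annotated transcript and library, with 2 decimals, on the B73 gene models whose IDs begin with Zm00001eb. Trimmomatic 0.36, HISAT2, RSEM and DESeq2 are named, without role or order, per the submitters' processing notes. The genome build is not given in the sources used here. No header or label states the unit. The deposited values were read as FPKM, fragments per kilobase of transcript and per 1e6 fragments, because they carry decimals and because their sums differed between libraries and stayed between 416517 and 686251, which whole counts or a complete TPM column would not give. A TPM column from which other transcripts had been left out would look alike, so rescaling each library to the same sum (TPM) was carried as an alternative. FPKM depends on the mix of transcript lengths in a library, which can shift all genes of one library together.

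The number of reads per library is unknown, since no counts were used here. Steps of single reads were searched in the low values of genes with 1 transcript, by asking how many ratios between WT replicate 1 and each other library lay on ratios of small whole numbers. At the best shift between 13.8% and 14.9% of ratios did so, against 10.9% to 11.2% at a typical shift. No common step was read from this, and no interval or floor that needs depth is given. A value of exactly 0 in such a table can be a failed estimate, so it is written as listed at 0. The search for genes at 0 in 1 library and at 20 FPKM or more in the other 5 found 1 gene in WT replicate 2, 1 in edf1-D replicate 2 and 0 in each of the other 4 libraries.

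Transcript values were summed to 44303 genes. Genes with at least 0.5 FPKM in at least 3 libraries were tested, which left 18719. This minimum was set once the unit was known, since the planned filter needs counts. The planned main test was a count model, to be replaced by limma with an intensity trend on log2(value + 1) if no counts were present. That replacement was used, on the values as deposited, with no covariate and a pseudocount of 1 (limma 3.58.1, R 4.3.3). Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. On simulated data with the same means and spreads for the 18719 genes of the edf1-D against WT comparison, 20 of 100 genes changed by 1 on the log2 scale and 69 of 100 changed by 2 were recovered, with 3 false calls. The simulation held fewer changed genes than were called in the data. Its values were cut at 0, so falls of low genes were partly lost. These shares therefore need not describe the real test.

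Isoform shares were tested with limma on log2 of a transcript's FPKM over that of the gene's other transcripts, with 1 added to both. This was done in genes with 2 or more transcripts, a mean of at least 5 FPKM and at least 1 FPKM in every library, for transcripts with a mean share of 10% to 90%. Assigning short reads to isoforms leaves their shares less certain than gene totals. The isoform and listed-at-0 comparisons were added after seeing the data. Reads of near-identical copies may be split between gene IDs, so single IDs of multigene families are uncertain.

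The files leave the gene name column empty, and 0 of the IDs could be matched in the table of RefSeq genes used here, which is of the B73 assembly. No gene is therefore named, no coordinates are given, and the gene that carries the edf1-D mutation cannot be followed here. The 43 gene lists fixed before the data were examined (flowering time, clock, photosynthesis, hormones, defence, other tissues and others) need names, so 0 of them were tested. By the rule fixed for that case, the text gives the 2 gene IDs that rose most and the 2 that fell most, among genes past the threshold with at least 5 FPKM in the higher group and no overlap between the libraries of both groups.

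The order of changed genes was tested with windows of 50 consecutive tested genes. The plan was to use positions. As none were paired with the IDs, the order of the IDs was used. That these IDs are numbered along the chromosomes is background knowledge that was not checked here, and windows may cross chromosome ends. The densest window was compared with 10000 random placements (one-sided permutation test, NumPy 2.4.6). In 100 simulated random placements over 18719 genes 5 passed a p of 0.05, and a planted group of neighbours was found. Dense blocks are the union of windows holding at least 11 changed genes, a count reached anywhere by at most 1% of random placements. Fisher's exact tests used SciPy 1.17.1.

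The alternatives were median-ratio (RLE) and upper quartile scaling, rescaling to TPM, quantile normalization, other filters, other pseudocounts, the replicate number as a block, each library left out in turn, stricter thresholds and 1 test per transcript.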

Results

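The series compares the leaf transcriptome of the edf1-D mutant of maize with that of its W22 background. W22 is a maize inbred line, and the suffix D by convention marks a dominant allele in maize. There were 3 WT and 3 edf1-D libraries. Each table listed 77341 transcripts of 44303 genes, of which 28954 had a single transcript and 15349 had 2 or more. Between 24187 genes (edf1-D replicate 3) and 25397 genes (WT replicate 2) had a value above 0, and between 15087 and 16915 genes, in the same libraries, reached 1 FPKM. The 10 most abundant genes held between 9.44% and 11.1% of a library's FPKM.

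The libraries grouped by genotype. Across the 18719 tested genes, Pearson's r of log2(FPKM + 1) lay between 0.957 and 0.978 for the 6 pairs of the same genotype, and between 0.917 and 0.948 for the 9 pairs across genotypes. These correlations are across genes, which are not independent replicates. The first principal component held 42.0% of the variance and separated WT (scores of -52.8 to -27.5) from edf1-D (33.6 to 42.8). The second held 28.9% and separated libraries within both genotypes, with edf1-D replicate 2 at 46.9 and WT replicate 1 at 24.0 on one side, and WT replicate 3 at -43.9 and edf1-D replicate 3 at -33.9 on the other.

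**Figure D1:**
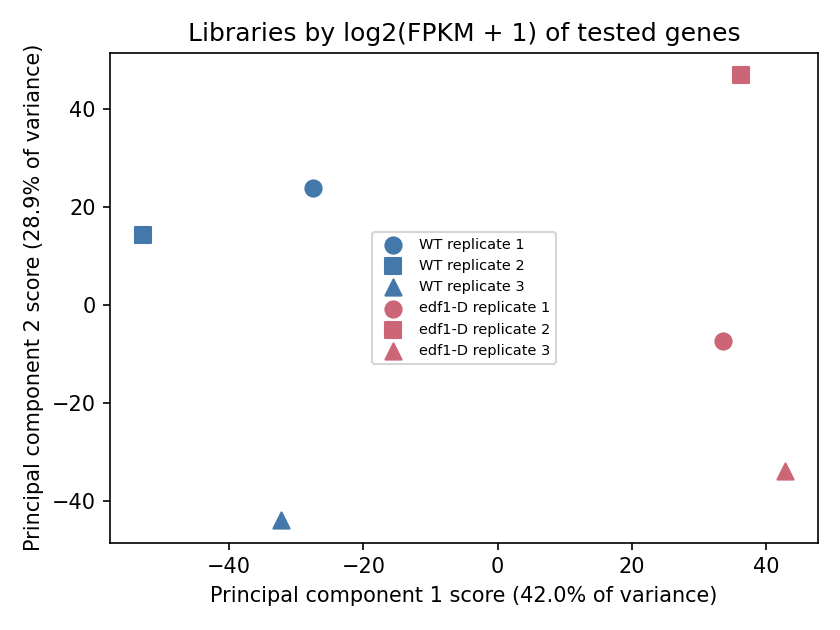
Principal component scores of the 6 libraries from log2(FPKM + 1) of the 18719 tested genes, with component 1 (42.0% of variance) on the x axis and component 2 (28.9%) on the y axis; colours are genotypes and symbols replicate numbers. WT libraries lie at or below -27.5 and edf1-D libraries at or above 33.6 on component 1.

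Leaves of edf1-D plants differed from WT leaves in 681 genes, 3.64% of those tested. Of these, 271 genes were higher and 410 lower in edf1-D (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change of the called genes was 1.45 in size among the higher and 1.39 among the lower. A change of at least 1 on the log2 scale was seen in 242 of the higher and 342 of the lower genes, and one of at least 3 in 20 and 22. None of the 681 genes had overlapping libraries between genotypes. Among all tested genes 26.3% did not overlap, where chance gives 10% for 3 against 3.

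Changed genes were found among low and abundant genes. Among those with a mean under 2 FPKM 3.81% were called (82 higher, 115 lower), among those from 2 to 10 FPKM 3.90% (101 higher, 174 lower), among those from 10 to 50 FPKM 3.43% (64 higher, 101 lower), and among the 1690 genes at 50 FPKM or more 2.60% (24 higher, 20 lower). How these shares run with abundance turned with the scaling: after quantile normalization they were 7.06%, 8.50%, 14.5% and 23.3% from the lowest to the highest class. The balance of directions followed the scaling of the libraries. Higher genes made up 39.8% of the calls on the deposited values, 58.2% after median-ratio scaling (1275 higher, 915 lower), 49.3% after quantile normalization (1012 higher, 1042 lower) and 28.0% after rescaling to TPM (597 higher, 1533 lower). The median log2 change of all tested genes was -0.12 on the deposited values and 0.00, -0.01 and -0.22 under these scalings. Such shifts are small against the changes of the called genes. The number of calls also depended on single libraries: without WT replicate 2 there were 168 higher and 199 lower genes, without WT replicate 3 there were 164 and 315, without edf1-D replicate 1 there were 122 and 170, and without edf1-D replicate 3 there were 161 and 168.

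**Figure D2:**
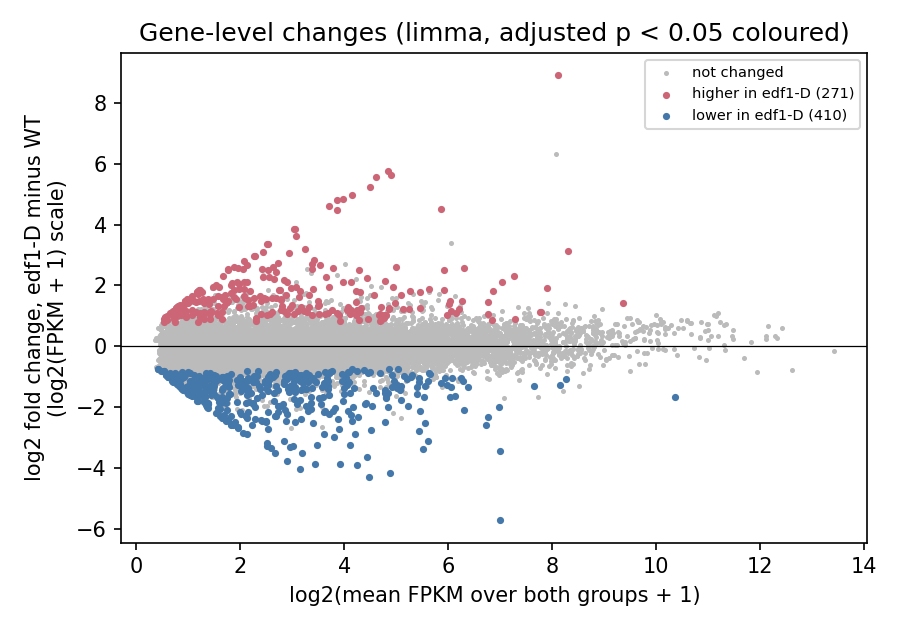
Log2 fold change of each of the 18719 tested genes (y axis, edf1-D minus WT, on the log2(FPKM + 1) scale) against its mean abundance (x axis, log2(mean FPKM + 1)); grey points did not pass the test, red points are the 271 higher genes and blue points the 410 lower genes. The highest point is the gene at 8.91.

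The gene with the largest rise was Zm00001eb382460, which has a single annotated transcript. It was listed at 0 in WT replicates 1 and 3 and at 0.48 FPKM in WT replicate 2, and stood at 551 ± 64.9 FPKM (SD, n = 3) in edf1-D. Its log2 fold change was 8.91 ± 0.21 (SE; limma adjusted p = 1.9e-06). As WT lay near 0, the pseudocount sets the size of this value, which was 11.6 ± 0.64 (SE) with a pseudocount of 0.1 and 12.2 ± 0.82 (SE) with TPM plus 0.1. Next came Zm00001eb275480, listed at 0 in every WT library and at 55.2 ± 16.8 FPKM (SD, n = 3) in edf1-D (limma adjusted p = 2.4e-05). Its log2 fold change depended on the pseudocount in the same way, with 5.77 as reported, 9.07 with a pseudocount of 0.1 and 9.89 with TPM plus 0.1.

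The largest fall was that of Zm00001eb184760, from 250.8 ± 77.5 FPKM in WT to 3.71 ± 1.17 FPKM in edf1-D (SD, n = 3 each). Its log2 fold change was -5.73 ± 0.27 (SE; limma adjusted p = 4.6e-05). Zm00001eb293080 fell from 41.6 ± 16.9 FPKM to 1.10 ± 0.55 FPKM (SD, n = 3 each), a log2 fold change of -4.29 ± 0.34 (SE; limma adjusted p = 0.00052). Over the 18 settings in which these 4 genes were tested, each passed the threshold every time, with adjusted p of at most 0.0057. The files pair none of the 4 IDs with a name, and whether one of them is the edf1 locus is not given in the sources used here.

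**Figure D3:**
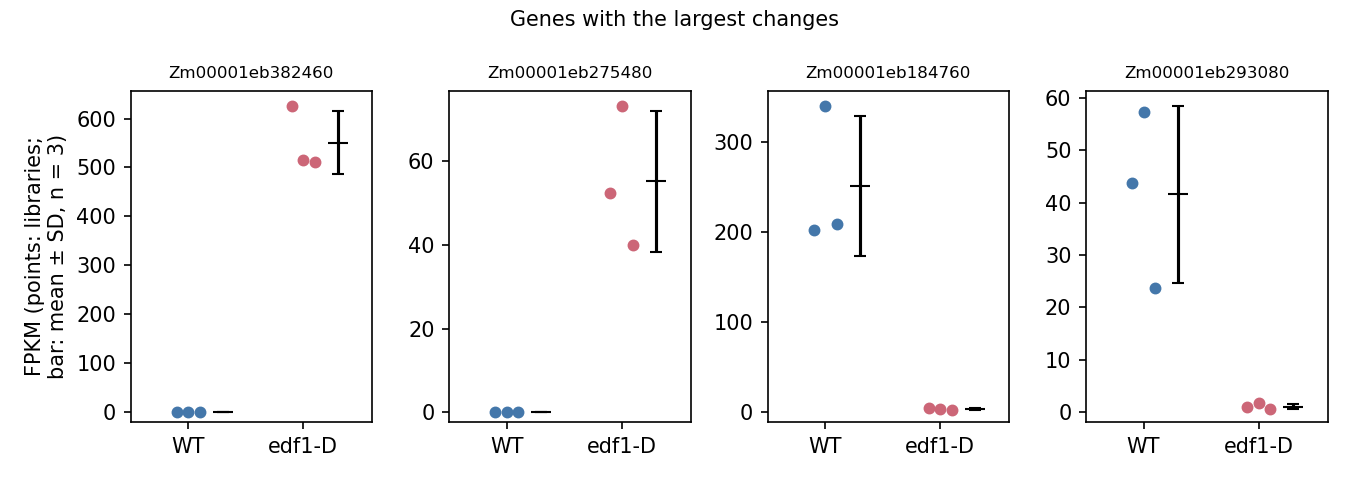
FPKM in each library (points), with the mean ± SD of 3 libraries beside them, for the 2 genes that rose most and the 2 that fell most; the y axes are linear, start near 0 and differ between panels. In each panel the 3 libraries of one genotype lie apart from the 3 of the other.

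Some genes were listed only in one genotype. A set of 29 genes was listed at 0 in every WT library and at 1 FPKM or more in every edf1-D library, with a median of 2.55 FPKM and a maximum of 55.2 FPKM in edf1-D. The opposite pattern was held by 27 genes, with a median of 3.16 FPKM and a maximum of 15.7 FPKM in WT. Of these 56 genes, 28 and 27 were also called by limma. The other splits of the 6 libraries into 3 and 3 gave at most 9 such genes, but they mix the genotypes, so this is no chance level. With the minimum set to 0.5 FPKM the counts were 47 and 45, and with 2 FPKM they were 13 and 14. Since the depth is unknown, a gene listed at 0 may have been below detection rather than absent.

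Transcript composition could be tested in fewer genes than total abundance, and with another measure, so the counts of both are not compared. Of 2671 genes with 2 or more usable isoforms, 33 showed a change in the share of at least 1 isoform (limma, adjusted p under 0.05), in 57 of the 5643 transcripts tested. In 11 of the 33 the gene total had also changed. The leading isoform was one in all 3 WT libraries and another in all 3 edf1-D libraries in 30 of 5832 genes. The other splits of the libraries gave 4 to 22 such genes. They mix the genotypes, so they are no chance level, and whether 30 is above chance cannot be told. Leaving out WT replicate 2 or edf1-D replicate 1 lowered the 33 genes to 21, and taking the replicate number as a block lowered them to 17.

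Changed genes were not spread evenly over the order of the gene IDs. These IDs are taken to be numbered along the chromosomes, which the files do not show and which was not checked, and a window may cross from one chromosome to the next. The densest window of 50 consecutive tested genes held 17 changed genes, where 1.82 would be held on average and the highest of 10000 random placements held 13 (one-sided permutation p = 1e-04, the smallest these placements can give). Windows with at least 11 changed genes merged into 6 blocks. These blocks held 671 tested genes, 3.58% of the total, and 146 changed genes, 21.4% of the total. Their extent depended on the scaling: after quantile normalization, with more changed genes, 7 blocks held 605 tested and 233 changed genes, and 427 of the 671 genes were still in a block. The densest window then held 26 changed genes, and 28 with TPM plus 1 (one-sided permutation p = 1e-04 for both). Each of the 6 blocks held genes that were higher and genes that were lower in edf1-D, 60 and 86 altogether. The largest block spanned 248 tested genes, of which 26 were higher and 35 lower. Its directions were uneven, with 2 higher and 14 lower genes in one window of 50 and 11 higher and 3 lower in another. The test took only the most one-sided window, the first of these. Its imbalance was past chance before adjustment over the 6 blocks (permutation p = 0.0397, Benjamini-Hochberg adjusted p = 0.238). Outside the blocks 2.96% of tested genes were changed. These were not evenly spread either, since windows just under the cut of 11 count as outside. One such window held 3 higher and 6 lower genes and another 7 higher and 2 lower, while many windows held none. Whether these windows are past chance was not tested. The blocks therefore mark the densest windows and need not hold all of the clustering.

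Because the blocks were chosen for holding changed genes, the enrichment was also measured on genes that had not been used to find them. When blocks were found on every other tested gene, the genes in between were changed in 28 of 132 cases (21.2%) inside and in 336 of 9227 cases (3.64%) outside, an odds ratio of 7.12 (95% interval 4.45 to 11.1; two-sided Fisher's exact p = 1.05e-13). The interval and the p-value treat genes as independent, which neighbours need not be. Copies or shared reads can fall on both sides of this split, and both sides rest on the same 6 libraries. Of the 4 genes given by ID, Zm00001eb184760 lay inside a block. Zm00001eb382460, Zm00001eb275480 and Zm00001eb293080 lay outside, with 1, 1 and 0 other changed genes among their 50 nearest tested genes. Of the 56 genes listed at 0 in one genotype, 10 lay in the blocks, 5 of them listed at 0 in WT and 5 in edf1-D. As 28 and 27 of the 56 were called genes, which had been used to find the blocks, this count is no separate measure of enrichment. Of all changed genes 21.4% lay in the blocks. The densest window kept a permutation p of 1e-04 when any 1 of the 6 libraries was left out, with between 12 and 17 changed genes.

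**Figure D4:**
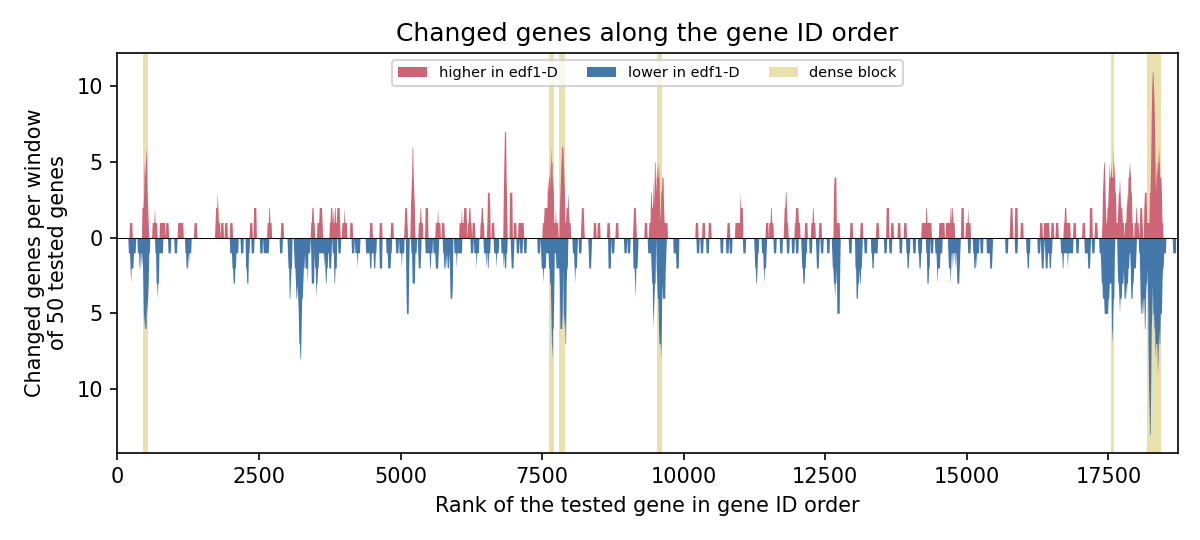
Changed genes in each window of 50 consecutive tested genes (y axis, genes higher in edf1-D upward in red, lower downward in blue) along the rank of the gene in gene ID order (x axis, 18719 tested genes); yellow bands are the 6 dense blocks. Each block holds red and blue, which peak at different ranks inside the widest band, and the widest band, of 248 tested genes, lies near the end of the order.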

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

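The number of calls depended on the processing. Counts of higher and lower genes, 271 and 410 as reported, were 1275 and 915 with median-ratio scaling, 1287 and 912 with upper quartile scaling, 597 and 1533 with TPM plus 1, 544 and 1420 with TPM plus 0.1, and 1012 and 1042 with quantile normalization, which was added after seeing the data. These scalings included 660 to 677 of the 681 genes. Without a filter there were 186 and 232, and at an adjusted p under 0.01 there were 104 and 133. With 1 library left out, the counts ran from 122 to 229 higher and from 168 to 351 lower genes, and 280 to 461 of the 681 were called again. Since no called gene had overlapping libraries, its direction could not turn in these fits. Without WT replicate 1 and edf1-D replicate 2 together, an alternative added after seeing the data, they were 345 and 644. The other settings stayed within 1.5 times, among them the pseudocount of 0.1, robust variances and 1 test per transcript, also added after seeing the data, as were the alternatives for isoforms and genes listed at 0. Whether the replicate numbers pair the samples stays open: deviations from the group means of libraries with the same number correlated at -0.19, -0.01 and 0.35 across genes. The replicate block gave 360 higher and 591 lower genes, 585 of the 681 among them, and 17 instead of 33 genes with an isoform share change. Leaving out 1 library gave 21 to 32 such genes. Genes listed at 0 in WT or edf1-D only, 29 and 27, were 47 and 45 at 0.5 FPKM and 13 and 14 at 2 FPKM. The cause of these differences was not tested. The clustering in ID order passed in all 11 alternatives, with p of at most 0.0025, and the 4 genes given by ID in all 17. Planned edgeR, DESeq2 and limma-voom fits, and all gene list tests, were not run, since no counts and no gene names were at hand. The unknown depth limits genes near 0. Of 10 splits of the 6 libraries the real one gave 681 changed genes, and the highest other gave 2. For isoform share changes the real split gave 33 genes and the highest other 1. In both cases 1 of the 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05. The other splits put libraries of both genotypes into each group, so the genotype difference widens their spread and lowers their counts. Their counts are therefore no chance level.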

Other observations

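The tests on bins of 10 genes and on directions inside the blocks were chosen after the pattern had been seen, as were the single-library values and the other isoform fits inside the blocks; the test against random placement was planned for positions and applied to ID order instead, a choice recorded after the pattern had been seen; the thinning, isoform and deviation tests were written before their results were known.

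Changed genes lay together in gene ID order, in 6 blocks that held 146 of the 681, and random placement is argued against by the permutation p of 1e-04. Genes of a block regulated together in one direction would move alike, but adjacent changed genes in the blocks moved the same way in a share of 0.543 of 140 pairs (95% exact interval 0.457 to 0.627, which treats pairs as independent), where 0.516 follows from the overall directions, while shorter one-sided stretches stay open in the largest block (permutation p = 0.0397, adjusted 0.238), and in 2 blocks the interval of this share alone reaches above 0.8. Whether tandem copies or shared reads among near neighbours are the cause stays open. Bins of 10 tested genes, each counted once, still lay together (one-sided permutation p = 0.0021). That test, chosen after the pattern had been seen, argues against near copies as the whole cause only in the densest run of 10 bins. It says nothing of the other blocks. Keeping only every 10th gene left 5 of 10 thinned sets past p 0.05, where chance alone gives 0.5. The bound set beforehand counted 5 sets for this explanation, although each set held only 58 to 79 changed genes. A candidate explanation, if the IDs follow the chromosomes, is that edf1-D and W22 plants differ in DNA sequence over a few segments. Linked or residual donor sequence that accompanies a mutation would give such segments. However, genes that set a single library apart also lay together in ID order. The densest windows held 15 in edf1-D replicate 2 and 7 in WT replicate 3 (one-sided permutation p = 0.001 for both). The other libraries did not pass. The windows overlap and both began past the last block, at ranks 18554 and 18569 against its end at 18430. At this site, outside the blocks, clustering thus arose without a difference between the genotypes. Clustering alone therefore does not single out differing segments. Among genes whose total was not called as changed, isoform shares changed in 7 of 77 genes inside the blocks and in 15 of 2507 outside. The odds ratio was 16.5 (95% interval 5.53 to 44.8; two-sided Fisher's exact p = 1.89e-06), and 26.2 (6.74 to 88.6) with blocks redrawn after quantile normalization. The intervals of these odds ratios and the p-value treat genes as independent. Changes in total that were missed may be more frequent among the genes inside, where 21.8% of tested genes were called against 2.96% outside. With the replicate number as a block in the isoform fit, the genes were 5 of 77 and 6 of 2507, an odds ratio of 28.8 (6.78 to 116), and the 7 other isoform fits gave at least 22.1. Whether genes there differ in expression or in how well their reads match the B73 models was not tested, as reads and variants were not used here, and an effect of the edf1-D mutation on the 535 changed genes outside the blocks stays open as well.

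Deviations of the libraries from their group means correlated across genes between the genotypes, in both directions. WT replicate 1 stood at -0.192, 0.360 and -0.273 with edf1-D replicates 1, 2 and 3, WT replicate 2 at 0.070, -0.009 and -0.053, and WT replicate 3 at 0.145, -0.390 and 0.352. Deviations from a mean of 3 libraries sum to 0 in each genotype, so positive and negative pairs must occur together and the 9 values are not independent. The RNA of the last 1000 gene IDs does not account for most of the value of 0.360, which was 0.308 without them. Without these IDs, WT replicate 3 went from 0.352 to 0.267 with edf1-D replicate 3 and from -0.390 to -0.319 with edf1-D replicate 2. The values of WT replicate 2, near 0 with and without them, moved little and in both directions. Whether the difference in total FPKM accounts for the value of 0.360 stays open: it was 0.343 after quantile normalization, but a correlation across genes already takes out a shift common to all genes. How large such correlations become by chance was not tested. The labels give no batch, harvest hour or plant, and no biological explanation was tested.

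The last 1000 gene IDs held 2.47% of the FPKM in WT replicate 3 and 1.76% in edf1-D replicate 3, against 0.985% in WT replicate 1, 1.08% in WT replicate 2, 1.20% in edf1-D replicate 1 and 0.899% in edf1-D replicate 2. In 1 window of 50 tested genes near the end of the ID order, edf1-D replicate 2 lay outside the range of the other 5 libraries by more than 1 on the log2 scale in 15 genes, 14 of them lower, and in an overlapping window WT replicate 3 did so in 7 genes, all 7 higher. Against the densest window of 1000 random placements of such genes, both had a one-sided permutation p of 0.001, the smallest these placements can give. The densest windows of the other 4 libraries, at other ranks, held 4 genes in WT replicate 1, 4 in WT replicate 2, 2 in edf1-D replicate 1 and 3 in edf1-D replicate 3, and did not pass (one-sided permutation p = 0.067, 0.608, 0.983 and 0.331). Over all tested genes, edf1-D replicate 2 stood above the other 5 libraries in this way in 197 genes and below them in 63, WT replicate 2 in 129 and 22, WT replicate 3 in 18 and 109, edf1-D replicate 3 in 5 and 48, WT replicate 1 in 43 and 38, and edf1-D replicate 1 in 17 and 24.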
